A study of Caenorhabditis elegans with 24 samples.

How the data were processed

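RNA was measured in whole Caenorhabditis elegans of the strains N2 and CF1041, daf-2(e1370), on adult days 1, 4, 7 and 11. Per the labels' protocols, embryos from bleaching were kept in buffer for 16 hours at 20°C, worms then grew on OP50 bacteria, FUDR was added from the last larval stage so that no progeny hatched, RNA was extracted with a phenol-based reagent, and stranded libraries were made from total RNA after ribosomal RNA depletion. The deposited values are expected counts per gene made by the authors, which need not be whole; between 929 and 1198 values per library were not whole, and all were rounded to whole numbers here. The submitters' processing notes name STAR 2.7.0e, RSEM 1.3.1 and the builds WBcel235 and ce11 without saying which step each served. The tables hold 46904 gene identifiers, of which 46817 were found in the Ensembl 115 annotation used here for symbols, types and positions on WBcel235. The other 87 held at most 0.0089% of a library's counts. Ribosomal depletion and the use of FUDR bear on the levels of ribosomal RNA and of embryo and germline transcripts.

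Samples were grouped by strain and age from the labels, 3 libraries in each of 8 groups, with between 20660999 and 32655703 expected counts each. No 2 libraries of a group held the same counts within sampling noise (lowest median chi-square 3.37, between N2 day 4 libraries 1 and 2). Genes were kept by edgeR's filterByExpr over the 8 groups, which left 16698, and scaled by TMM factors. All 24 libraries entered 1 model with a mean per group (biological coefficient of variation 0.273), and 16 contrasts were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The contrasts were each later age against day 1 and day 11 against day 4 in each strain, the strains at each age, and the differences between strains of those age changes. Log2 CPM used a prior count of 2, log2 fold changes edgeR's lower default. Each standard error is the change's size over the square root of its F value. Where a group was at 0 in all its libraries, the fold is a bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio has a 95% interval.

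The tests, the gene lists, the rule for naming genes and the other settings listed here were set before the data were examined. The rule took, in each of 5 main comparisons (day 11 against day 1 in each strain, the strains at days 1 and 11, and strain by age), the 5 largest rises and 5 largest falls among protein-coding genes with a gene-class symbol that passed, had a mean of at least 10 CPM and did not overlap between the groups (no such demand for strain by age). It also took up to 4 of the most changed members per list that passed at 10 CPM or more, or else the member with the highest mean, and always daf-2, daf-16, sod-3, mtl-1, vit-2, hsp-16.2 and tts-1. The other comparisons took the 3 largest rises and falls. The 43 lists were matched by symbol, or for mitochondrial genes by position, and tested as sets with limma's camera at a preset correlation of 0.01 and, as an alternative, an estimated correlation, with Benjamini-Hochberg adjustment over the lists. No member was found for the symbols trp-3, ssp-11, msd-3, daf-21, iftb-1, eft-1, eft-2, eft-3, eft-4, hrp-1 and mog-6. RSEM divides reads between near-identical copies, as in the histone and nspc families, so their counts are uncertain.

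Libraries with the same replicate number deviated together from their group means: in all 24 a library correlated best with others of its number, with a mean correlation of 0.23 for those numbered 1, 0.24 for 2 and 0.43 for 3. The numbers were taken to pair the samples where every pair's correlation was above 0.1, which held for N2 at day 11 against day 1, for all 4 age comparisons in daf-2 and for the strains at all 4 ages. Alternatives were DESeq2's Wald test, RLE, upper-quartile and library-size scaling, no filter, a filter at 1 CPM in 3 libraries, a fit of only the groups compared, protein-coding genes only, a replicate block, and each library left out in turn. Simulated counts were independent, unlike the data, with only 200 changed genes at 10 CPM or more. In N2 at day 11 against day 1 (16261 genes), 56 of 100 2-fold, 99 of 100 4-fold and 9 unchanged genes were called. For strain by age (16238 genes) these numbered 26, 81 and 3. Work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.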

Results

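Whole worms of 2 Caenorhabditis elegans strains were profiled at 4 ages: the wild-type strain N2 and CF1041, a strain carrying daf-2(e1370). The gene daf-2 encodes the worm's insulin/IGF-1 receptor, and e1370 is a reduced-function missense allele that is widely studied for its long life. RNA was sequenced on adult days 1, 4, 7 and 11, with 3 libraries per strain and age, which gave 24 libraries in 8 groups. Each library held between 20660999 and 32655703 expected counts over genes, and between 18073 and 20652 genes were above 0. The design addresses how gene expression changes with age in each strain and where the strains differ. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Intervals and floors given for counts cover counting error only.

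Transcripts of daf-2 itself (WBGene00000898) were at mean levels between 170 and 258 CPM (counts scaled to the size of the library) over the 4 N2 groups and between 203.5 and 276 CPM over the 4 mutant groups. The difference between the strains did not pass at day 1 (log2 fold change 0.26 ± 0.26, SE, n = 3 and 3, adjusted p = 1) or at day 11 (-0.04 ± 0.26, adjusted p = 0.988) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A missense allele need not change transcript level, so these values do not check the strain labels. Ribosomal RNA, mitochondrial and cytosolic, made up 3.9% to 14.55% of the counts. It made up 7.92% to 14.55% in the 8 libraries numbered 3, against 5.59% to 8.83% in those numbered 1 and 3.9% to 9.62% in those numbered 2.

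**Figure D1:**
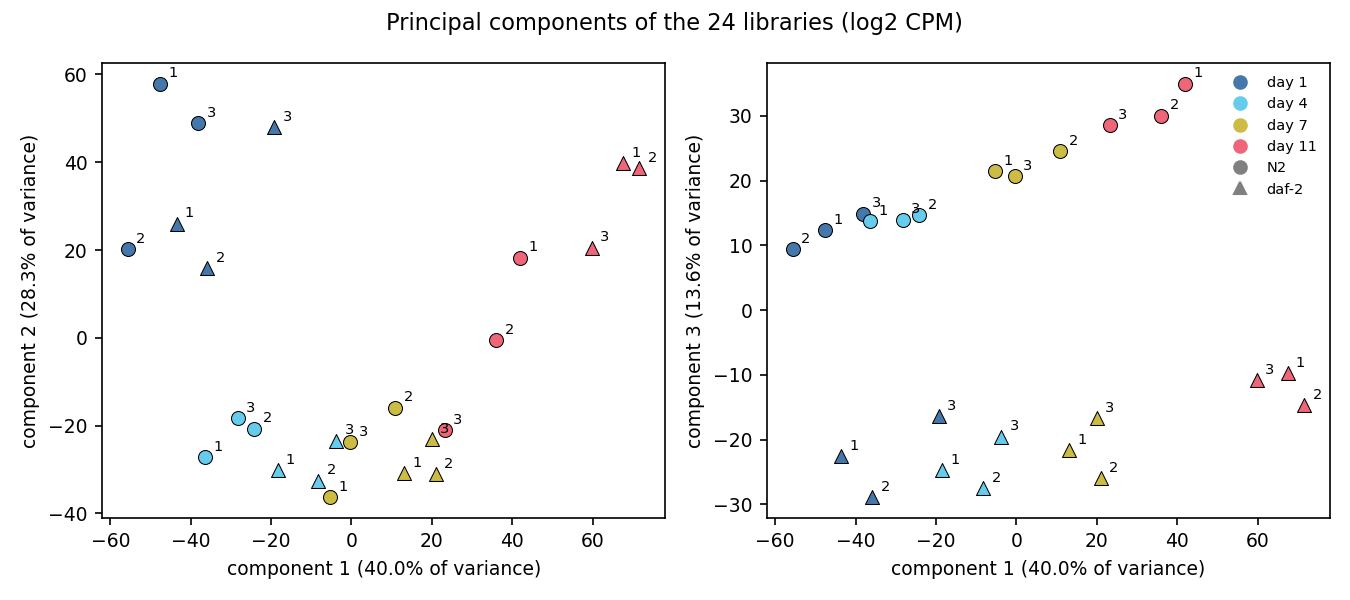
Principal components of log2 CPM over the 1000 most variable genes, with 1 point per library (color, day of adulthood; circle, N2; triangle, daf-2; digit, replicate number) and axes in component units. Component 1 runs from day 1 to day 11, and component 3 (13.6% of the variance) parts all 12 N2 libraries from all 12 daf-2 libraries.

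The first comparison asked which genes changed between day 1 and day 11 in wild-type worms. Cuticle collagen genes, which encode the structural proteins of the worm's outer coat, held the largest changes among named genes. Transcripts of col-93 (WBGene00000668, chromosome III from position 10984552 on WBcel235) fell 6590-fold (log2 fold change -12.69 ± 0.70, SE, n = 3 and 3, adjusted p = 1.51e-10). Those of col-20, col-94 and col-159 fell 435-fold, 394-fold and 334-fold, and col-92 had 2 counts over the day 11 libraries against 10088 at day 1, a ratio of 5910 (95% counting interval 1640 to 48800). Another collagen gene, col-183, rose 824-fold (log2 9.69 ± 1.02, adjusted p = 3.49e-07). The invertebrate-type lysozyme gene ilys-3 (WBGene00016670, chromosome IV from position 2464456) rose 751-fold (log2 9.55 ± 0.75, adjusted p = 7.36e-09) and its relative ilys-2 86.2-fold (log2 6.43 ± 0.82). The phosphate transporter family gene pitr-4 rose by a log2 change of 7.48 ± 0.46 and the neuropeptide-like gene nlp-39 120-fold (log2 6.90 ± 0.52).

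Among the genes followed in every comparison, the metallothionein gene mtl-1 rose 34.6-fold in N2 (log2 5.11 ± 0.63, adjusted p = 2.15e-06) and the long non-coding RNA tts-1 28.6-fold (log2 4.84 ± 0.48). The small heat shock gene hsp-16.2 rose (log2 3.32 ± 1.02, adjusted p = 0.0126), a call that ended without N2 day 1 library 1 (adjusted p = 0.0581) or library 2 (adjusted p = 0.057). The mitochondrial superoxide dismutase gene sod-3 fell 2.33-fold (log2 -1.22 ± 0.31, adjusted p = 0.00338). Values of daf-2 (log2 0.60 ± 0.27, adjusted p = 0.073; adjusted p = 0.00349 with the replicate number as a block), of the FOXO gene daf-16 (0.79 ± 0.36, adjusted p = 0.0861) and of the yolk protein gene vit-2 (0.41 ± 0.56, adjusted p = 0.583) did not pass. Of 16698 genes tested with edgeR's quasi-likelihood test, 3752 rose and 3206 fell (9491 calls with the block). The change was at least 2-fold in 4248 of the 6958. The share of called genes that rose, 53.9%, was 65.4% with upper-quartile scaling and 69.5% with library size alone, which raised the median of all genes by 0.183 and 0.230 on the log2 scale, so changes of that size depend on the scaling.

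**Figure D2:**
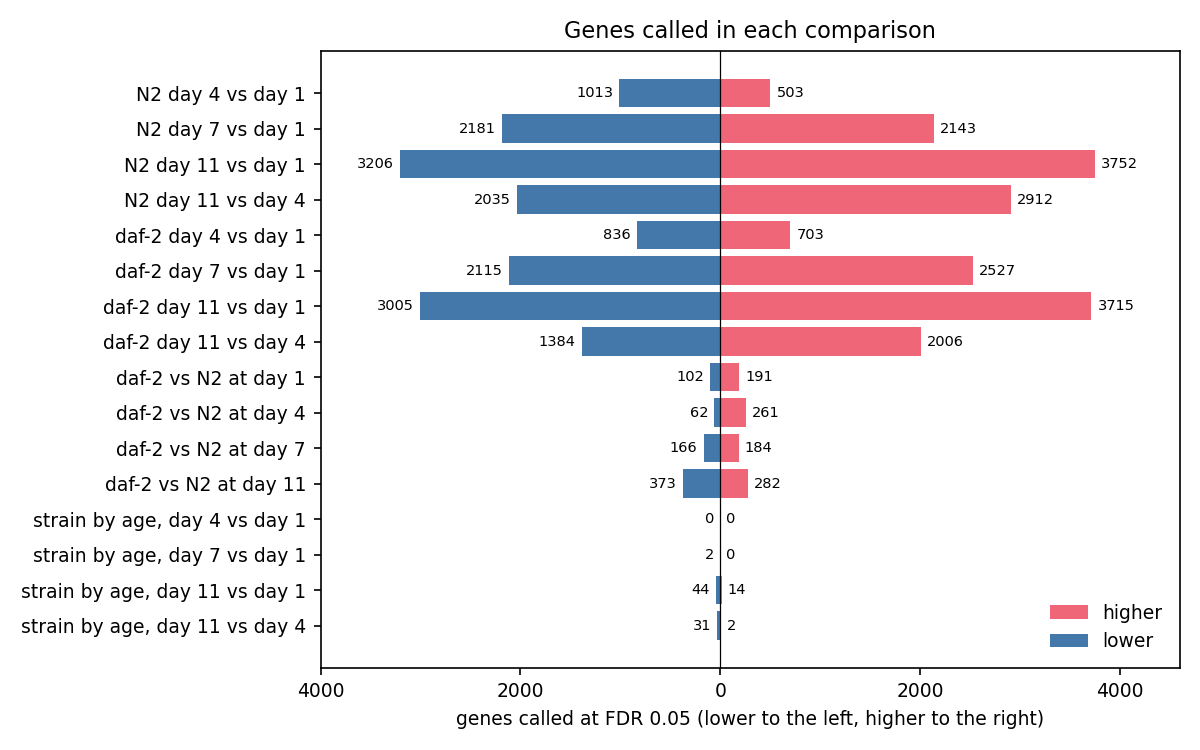
Number of genes called at a false discovery rate of 0.05 by edgeR's quasi-likelihood test in each of the 16 comparisons (bars to the right, higher; bars to the left, lower; x axis, genes). In N2 3752 genes rose and 3206 fell between days 1 and 11, against 282 higher and 373 lower in daf-2 than N2 at day 11.

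Genes of the cuticle, muscle and gut were among those that fell in N2. Of 151 tested collagen genes 76 fell and 19 rose (82 and 24 adjusted over the list alone), with a median log2 change of -1.77. Of 35 muscle structural genes 23 fell (23 adjusted over the list alone). They included the troponin T gene tnt-2 (-4.52 ± 0.50), the myosin light chain genes mlc-2 (-2.88 ± 0.24) and mlc-1 (-2.68 ± 0.36) and the troponin I gene unc-27 (-2.82 ± 0.34). Both lists were lower as sets by camera (adjusted p = 4.26e-18 for collagens and 7.58e-10 for muscle genes), although not when the correlation was estimated (adjusted p = 0.19 with an estimated correlation for collagens and adjusted p = 0.353 with an estimated correlation for muscle genes). Of 17 intestinal genes 7 fell and 1 rose (7 and 1 adjusted over the list alone), the falls including the acid phosphatase gene pho-1 (-3.31 ± 0.41), the actin gene act-5 (-2.72 ± 0.23) and the peptide transporter gene pept-1 (-1.74 ± 0.27). Intestinal genes gave camera adjusted p = 0.001 (adjusted p = 0.329 with an estimated correlation). Of the 6 vitellogenin genes, which encode yolk proteins, vit-3 (-5.54 ± 0.65), vit-4 (-5.21 ± 0.57) and vit-1 (-4.34 ± 0.57) fell (3 adjusted over the list alone). Vitellogenins gave camera adjusted p = 0.00318 (adjusted p = 0.411 with an estimated correlation). The yolk set test was no longer passed without the libraries numbered 3 (adjusted p = 0.131). The count of collagen genes that rose was 29 with the block, 12 without N2 day 1 library 1 and 10 without N2 day 11 library 3.

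Most mitochondrial ribosomal protein genes fell in N2, with many respiratory chain and mitochondrial chaperone genes. Of 70 mitochondrial ribosomal protein genes 67 fell (68 adjusted over the list alone), among them mrps-23 (-1.78 ± 0.22) and mrpl-12 (-1.74 ± 0.18). Of 43 nuclear-encoded respiratory chain and ATP synthase genes 28 fell (29 adjusted over the list alone), including nuo-6 (-1.21 ± 0.12), asg-2 (-1.18 ± 0.14) and cox-11 (-1.24 ± 0.21). The camera tests gave adjusted p = 1.11e-23 for the ribosomal proteins and adjusted p = 1.79e-07 for the respiratory chain. Neither passed when the correlation was estimated (adjusted p = 0.0833 with an estimated correlation and adjusted p = 0.411 with an estimated correlation). Of 12 protein genes of the mitochondrial genome 10 fell (10 adjusted over the list alone; 6 without N2 day 11 library 2), including COX1 (-1.77 ± 0.40) and ND5 (-1.63 ± 0.33). Mitochondrially encoded genes gave camera adjusted p = 0.000611 (adjusted p = 0.453 with an estimated correlation). In the libraries numbered 3 these 12 genes lay 0.40 above their group means (log2, median), and ribosomal RNA made up 7.92% to 14.55% of their counts. Of 14 mitochondrial chaperones and proteases 10 fell (10 adjusted over the list alone), including hsp-60 (-1.82 ± 0.29). These chaperones and proteases gave camera adjusted p = 0.000182 (adjusted p = 0.304 with an estimated correlation).

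Genes for cytosolic protein synthesis and RNA processing were also among the falls. Of 31 aminoacyl-tRNA synthetase genes 18 fell (22 adjusted over the list alone), including vars-1 (-1.57 ± 0.12) and aars-1 (-1.37 ± 0.16). Synthetases gave camera adjusted p = 2.45e-07 (adjusted p = 0.411 with an estimated correlation). Of 67 splicing and RNA processing genes 30 fell (34 adjusted over the list alone), including gut-2 (-1.37 ± 0.22) and mog-2 (-1.21 ± 0.12). Splicing genes gave camera adjusted p = 7.07e-06 (adjusted p = 0.329 with an estimated correlation). Of 40 translation factor genes 17 fell and 1 rose (17 and 2 adjusted over the list alone), eif-2D (-1.36 ± 0.15) and eif-3.H (-1.08 ± 0.16) among the falls. Translation factors gave camera adjusted p = 9.03e-05 (adjusted p = 0.376 with an estimated correlation). Of 82 cytosolic ribosomal protein genes 22 fell (16 adjusted over the list alone), such as rpl-41.2 (-1.28 ± 0.26) and rpl-7A (-1.04 ± 0.25). Cytosolic ribosomal proteins gave camera adjusted p = 0.000342 (adjusted p = 0.678 with an estimated correlation). Of 20 nucleolar genes 12 fell and 1 rose (13 and 1 adjusted over the list alone), including rpoa-2 (-1.34 ± 0.17). Nucleolar genes gave camera adjusted p = 0.00154 (adjusted p = 0.464 with an estimated correlation). Of 31 proteasome subunit genes 11 fell (11 adjusted over the list alone), including pas-4 (-0.93 ± 0.17). Proteasome subunits gave camera adjusted p = 0.000182 (adjusted p = 0.535 with an estimated correlation). With the block the falls numbered 54 cytosolic ribosomal proteins, 28 translation factors (with 3 rises) and 24 proteasome subunits. The falls numbered 14 and 11 cytosolic ribosomal proteins without N2 day 11 libraries 1 and 3, 6 nucleolar genes without N2 day 11 library 3, and 18 proteasome subunits without N2 day 1 library 3.

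Metabolic genes changed in both directions in N2. Of 36 fatty acid enzymes 15 fell and 8 rose (15 and 8 adjusted over the list alone): the acyl-CoA dehydrogenase gene acdh-1 fell (-5.03 ± 0.51), as did the stearoyl-CoA desaturase gene fat-7 (-3.34 ± 0.43), while the lysosomal lipase gene lipl-1 rose (4.14 ± 0.69). The camera adjusted p was 0.000895 (adjusted p = 0.329 with an estimated correlation; adjusted p = 0.0507 without the libraries numbered 3), and 5 rose without N2 day 11 library 2 or library 3. Of 23 TCA and glyoxylate cycle genes 10 fell and 1 rose (10 and 1 adjusted over the list alone). Of these sucg-1 (-1.59 ± 0.18) and dld-1 (-1.62 ± 0.25) fell, and icl-1, the glyoxylate cycle gene, rose (1.62 ± 0.29), with a camera adjusted p = 0.0114 (adjusted p = 0.5 with an estimated correlation). Of 19 glycolysis genes 6 fell (6 adjusted over the list alone; 10 with the block), including gpd-2 (-0.94 ± 0.14) and tpi-1 (-0.80 ± 0.17). Glycolysis genes gave camera adjusted p = 0.0166 (adjusted p = 0.5 with an estimated correlation; adjusted p = 0.0694 without N2 day 1 library 1). Of 27 antioxidant enzyme genes 11 fell and 7 rose (13 and 7 adjusted over the list alone), with msra-1 lower (-4.16 ± 0.54) and sod-4 higher (1.65 ± 0.24). Antioxidant genes gave camera adjusted p = 0.15. Of 178 cytochrome P450, UDP-glucuronosyltransferase and glutathione S-transferase genes 53 fell and 32 rose (55 and 35 adjusted over the list alone), gst-27 falling (-3.71 ± 0.24) and ugt-18 rising (4.40 ± 0.42). The median of that list, -0.17, was 0.06 with library size alone, and camera gave adjusted p = 0.0635.

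More genes for defence, autophagy and the endoplasmic reticulum rose than fell in N2. Of 66 lysozyme, saposin-like and other antimicrobial genes 32 rose and 14 fell (35 and 15 adjusted over the list alone), the rises including nlp-34 (6.08 ± 0.46) and cnc-4 (5.43 ± 0.56). Antimicrobial genes gave camera adjusted p = 0.00733 (adjusted p = 0.464 with an estimated correlation). Of 142 C-type lectin genes 44 rose and 29 fell (46 and 31 adjusted over the list alone), with clec-7 higher (3.51 ± 0.47) and clec-47 lower (-6.47 ± 0.41). Lectins gave camera adjusted p = 0.534; 27 rose without N2 day 1 library 2. Of 15 endoplasmic reticulum chaperone genes 10 rose (12 adjusted over the list alone), including the calreticulin gene crt-1 (1.26 ± 0.21) and dnj-27 (1.23 ± 0.16). Chaperones of this list gave camera adjusted p = 0.00016 (adjusted p = 0.232 with an estimated correlation). Of 28 autophagy genes 11 rose (11 adjusted over the list alone), including the p62 homolog sqst-1 (2.47 ± 0.24) and atg-16.2 (1.27 ± 0.20). Autophagy genes gave camera adjusted p = 0.01 (adjusted p = 0.19 with an estimated correlation). Of 22 lysosomal protease genes 9 fell and 4 rose (9 and 4 adjusted over the list alone), asp-14 falling (-4.50 ± 0.27) and cpr-1 rising (3.30 ± 0.80). That list passed camera (adjusted p = 0.00968; adjusted p = 0.442 with an estimated correlation) but not with the block (adjusted p = 0.0826) or without the libraries numbered 3 (adjusted p = 0.0507). Of 14 small heat shock genes 7 rose and 3 fell (7 and 3 adjusted over the list alone), hsp-16.1 rising (3.72 ± 1.07). Small heat shock genes gave camera adjusted p = 0.636. The rises numbered 3 without N2 day 1 library 1 or library 2 and 4 without N2 day 11 library 3. Of 19 cytosolic chaperone genes 6 fell and 1 rose (6 and 1 adjusted over the list alone; 3 rose with the block), including dnj-13 (-0.75 ± 0.16). Cytosolic chaperones gave camera adjusted p = 0.292; the median of this list was -0.14, its mean 0.15, and its median 0.09 with library size alone.

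Genes named in earlier work as higher in daf-2 worms through the transcription factor DAF-16 (class I) mostly rose with age in N2. Of 18 tested, 13 rose and 2 fell (13 and 2 adjusted over the list alone), including the ferritin gene ftn-1 (4.82 ± 0.61) and the lysozyme gene lys-7 (4.46 ± 0.60) beside mtl-1 and tts-1, with a camera adjusted p = 5.46e-05 (adjusted p = 0.19 with an estimated correlation). Of 11 class II genes, lower in daf-2 in earlier work, 6 fell (6 adjusted over the list alone), including dod-17 (-4.16 ± 0.51) and dod-24 (-1.96 ± 0.51). Class II genes gave camera adjusted p = 0.00299 (adjusted p = 0.19 with an estimated correlation). Of 27 insulin-like peptide genes 9 rose and 2 fell (9 and 2 adjusted over the list alone), ins-7 rising 30.7-fold (4.94 ± 0.52) and ins-17 2.75-fold (1.46 ± 0.19). Insulin-like peptides gave camera adjusted p = 0.00962 (adjusted p = 0.335 with an estimated correlation; adjusted p = 0.0558 without a low-count filter). Of 14 genes of the insulin signalling pathway the kinase genes pdk-1 (0.97 ± 0.15), sgk-1 (0.95 ± 0.21) and akt-2 (0.90 ± 0.18) rose, and 1 fell (3 and 0 adjusted over the list alone; 2 fell with the block). Pathway genes gave camera adjusted p = 0.282.

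Of germline genes 18 fell in N2 and sperm genes went both ways. Of 33 germline proliferation and meiosis genes 18 fell (19 adjusted over the list alone; 11 without N2 day 11 library 3), including the synapsis genes htp-1 (-1.21 ± 0.16) and him-8 (-1.19 ± 0.12). Germline genes gave camera adjusted p = 2.71e-05 (adjusted p = 0.455 with an estimated correlation). Of 54 sperm genes 6 fell and 5 rose (1 and 2 adjusted over the list alone), with a median of -1.06 that was -0.28 without the libraries numbered 3. Sperm genes gave camera adjusted p = 0.131 (0.922, in the other direction, without those libraries, where 1 fell). These counts hung on single libraries: 21 fell without N2 day 11 library 1, 12 without N2 day 1 library 2, 2 without N2 day 1 library 3 and 1 without N2 day 1 library 1 or N2 day 11 library 2 or 3, and 2 or 3 rose without any one of N2 day 1 libraries 1 to 3 or N2 day 11 library 1. Sperm genes passed as a set with upper-quartile scaling (adjusted p = 0.0298), library size alone (adjusted p = 0.0187) and a fit of the compared groups only (adjusted p = 0.0391). Of 26 oocyte, eggshell and maternal genes the eggshell genes perm-4 (1.98 ± 0.30) and perm-2 (1.33 ± 0.26) rose (2 adjusted over the list alone). Oocyte genes gave camera adjusted p = 0.805. Of 18 zygotic embryo genes 3 fell, tbx-9 among them (-1.17 ± 0.19), and 1 rose (2 and 1 adjusted over the list alone; 5 fell with the block). Zygotic genes gave camera adjusted p = 0.343 and a median of -0.10 that was 0.09 with upper-quartile scaling. Of 27 cell cycle and replication genes 3 fell (1 adjusted over the list alone; 5 with the block), orc-1 among them (-0.90 ± 0.22). Cell cycle genes gave camera adjusted p = 0.382 and a median of -0.04 that was 0.15 with upper-quartile scaling. Of 69 histone genes, many of them near-identical copies whose counts are uncertain, 20 rose and 1 fell (12 and 1 adjusted over the list alone; 31 and 3 with the block). Histones passed camera with the block (adjusted p = 0.0376) and without the libraries numbered 3 (adjusted p = 0.00293), but not in the fit without these changes (adjusted p = 0.0913), and 8 rose without N2 day 1 library 1 or library 2 and 12 without N2 day 11 library 1 or library 3. Of 5 male neuron and seminal fluid genes 2 rose (3 adjusted over the list alone; 4 with the block; 1 without the libraries numbered 3), with a median of 1.53. These male genes gave camera adjusted p = 0.191; the most abundant of them, plg-1, was at log2 0.05 ± 0.30 (adjusted p = 0.911).

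Few nervous system genes changed in N2, and some receptor genes rose. Of 33 neuronal and synaptic genes 5 rose, including snb-1 (1.03 ± 0.12) and unc-33 (0.75 ± 0.17), and 2 fell (5 and 2 adjusted over the list alone). Neuronal genes gave camera adjusted p = 0.396. Of 30 FMRFamide-like neuropeptide genes 3 rose, flp-22 among them (0.76 ± 0.19; 3 adjusted over the list alone; 8 with the block). FMRFamide-like genes gave camera adjusted p = 0.618. Of 13 pharyngeal genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; 4 and 3 with the block). Pharyngeal genes gave camera adjusted p = 0.829, a median of 0.07 and a mean of -0.44; the muscle myosin gene myo-1 was at -1.30 ± 0.74 (adjusted p = 0.169; adjusted p = 0.00183 with the block). Of 212 nuclear hormone receptor genes 69 rose and 9 fell (66 and 9 adjusted over the list alone; 19 fell with the block; 45 rose without N2 day 1 library 1), nhr-61 rising (1.92 ± 0.29) and nhr-114 falling (-3.04 ± 0.36). Nuclear hormone receptors gave camera adjusted p = 0.00776 (adjusted p = 0.639 with an estimated correlation). Of 223 genes in the chemoreceptor list 67 rose and 10 fell (58 and 9 adjusted over the list alone; 16 fell with the block). The chemoreceptor list gave camera adjusted p = 0.00325 (adjusted p = 0.5 with an estimated correlation). That list was matched by symbol and took in 19 srlf and srpr genes, which are not chemoreceptors by name and include srlf-34 (5.31 ± 0.57); without them 58 of 204 rose and 7 fell. Of 352 F-box and MATH domain genes 74 rose and 36 fell (69 and 34 adjusted over the list alone; 70 fell with the block), bath-38 rising (1.53 ± 0.17) and fbxa-72 falling (-4.21 ± 0.48). F-box and MATH genes gave camera adjusted p = 0.396.

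**Figure D3:**
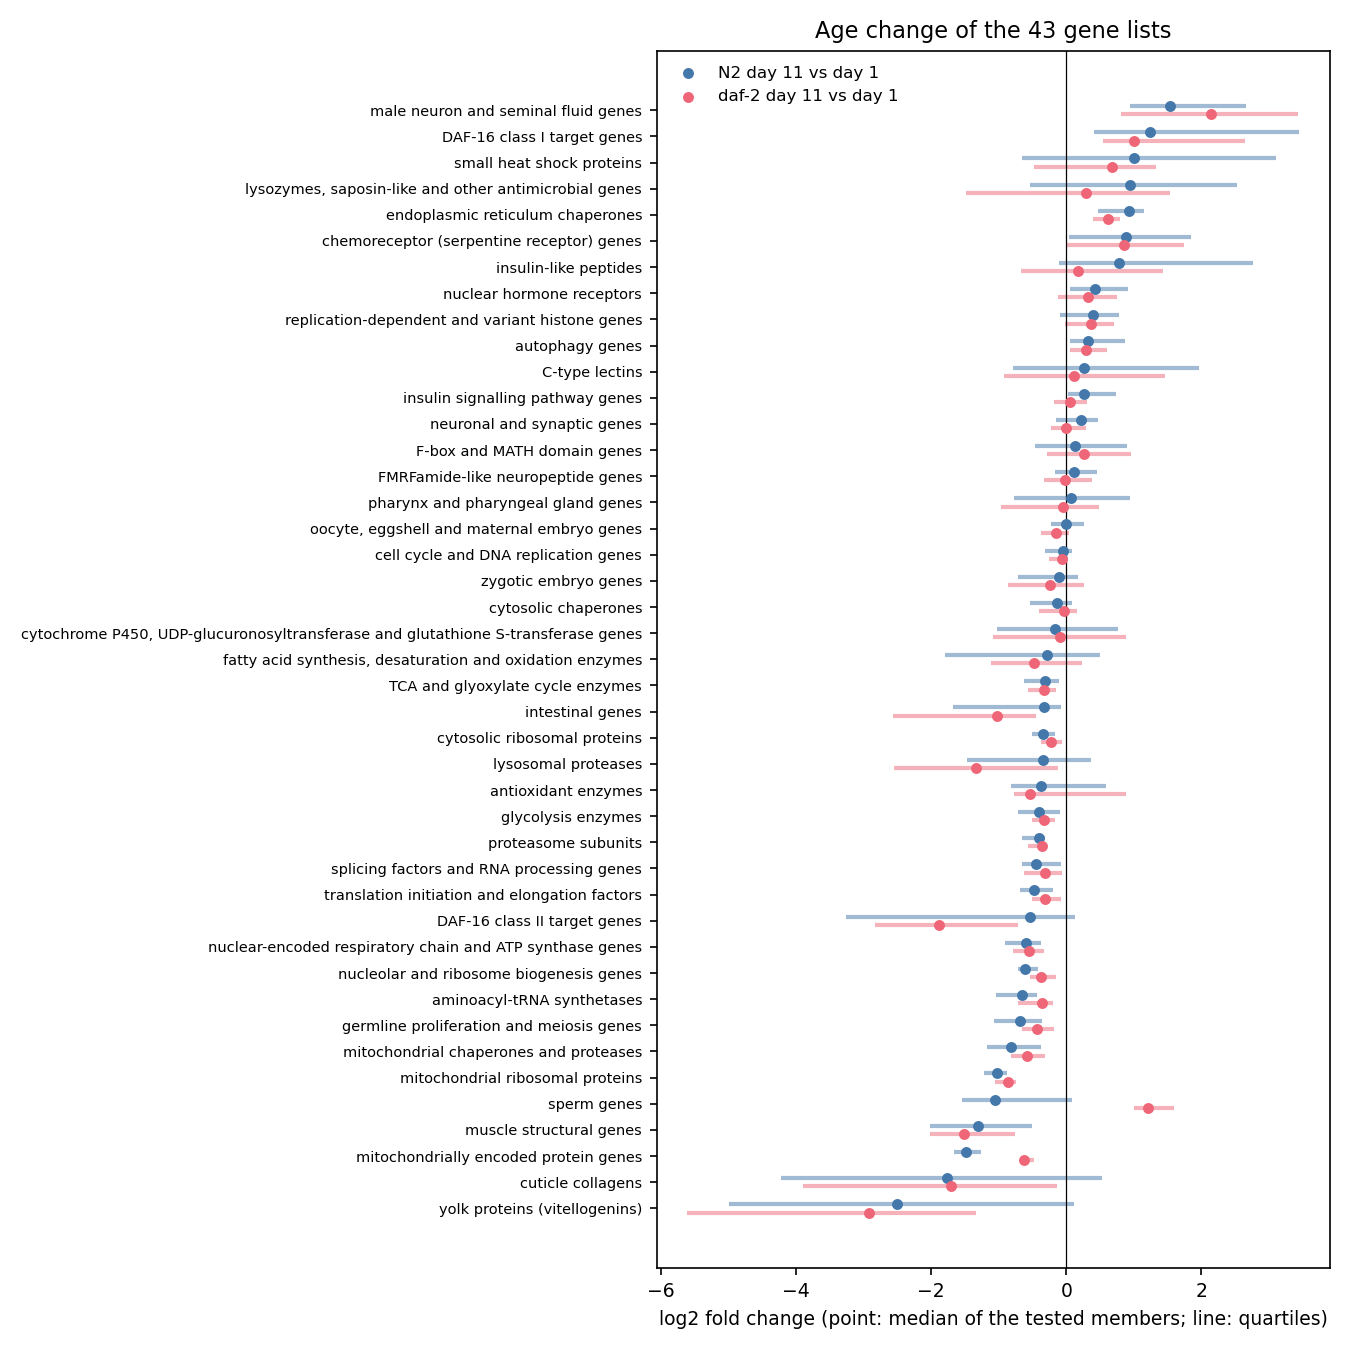
Median log2 fold change between days 1 and 11 (x axis) of the tested members of each of the 43 gene lists (y axis), in N2 (blue) and daf-2 (red), with lines from the lower to the upper quartile of the members. Collagen genes have medians of -1.77 and -1.70 and sperm genes of -1.06 in N2 and 1.21 in daf-2 (-0.28 and 2.52 without the libraries numbered 3); with other scalings the medians of the zygotic embryo list in N2, of the oocyte, FMRFamide-like and pharynx lists in daf-2, and of the cell cycle, cytosolic chaperone and cytochrome P450 lists in both change sign.

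The same ages were then compared in daf-2 worms. Collagens again held the largest falls among named genes: col-93 fell 13300-fold (log2 -13.70 ± 0.73, SE, n = 3 and 3, adjusted p = 8.37e-11), col-94 528-fold and col-20 502-fold, and col-92, at 0 in all 3 day 11 libraries, was at least 4600-fold lower (against 3 counts over the group). The hedgehog-related gene grd-3 fell 228-fold (-7.83 ± 0.61). The gene clx-1 had 45885 counts over the day 11 libraries against 3 at day 1, a ratio of 14300 (95% counting interval 4890 to 69300). The genes pitr-4 and col-183 rose 139-fold (7.12 ± 0.44) and 67.9-fold (6.08 ± 0.81), the saposin-like gene spp-27 86.0-fold (6.43 ± 0.79) and the cathepsin B family gene cpr-2 59.8-fold (5.90 ± 1.42, adjusted p = 0.00261). Of the genes followed throughout, mtl-1 rose 49.5-fold (5.63 ± 0.60) and tts-1 6.53-fold (2.71 ± 0.44), sod-3 fell 2.19-fold (-1.13 ± 0.30), and hsp-16.2 (1.54 ± 0.90, adjusted p = 0.181; adjusted p = 0.00352 with the block), daf-2 (0.31 ± 0.26, adjusted p = 0.369), daf-16 (0.84 ± 0.36, adjusted p = 0.0715) and vit-2 (-0.73 ± 0.57, adjusted p = 0.319) did not pass. By edgeR 3715 genes rose and 3005 fell (9486 calls with the block), 4283 of the 6720 by at least 2-fold. The share that rose, 55.3%, was 68.9% with upper-quartile scaling and 69.4% with library size alone, each of which raised the median of all genes by 0.202.

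Collagen, muscle, gut and yolk genes were among the falls in daf-2 too. Of 151 collagen genes 83 fell and 12 rose (87 and 14 adjusted over the list alone), and of 35 muscle genes 25 fell (27 adjusted over the list alone), including tnt-2 (-5.06 ± 0.52) and unc-54 (-3.10 ± 0.52). Camera gave adjusted p = 3.9e-21 for collagens (adjusted p = 0.107 with an estimated correlation) and adjusted p = 2.51e-13 for muscle (adjusted p = 0.315 with an estimated correlation). Of 17 intestinal genes 10 fell (11 adjusted over the list alone), including act-5 (-3.62 ± 0.24), pept-1 (-3.49 ± 0.29), the intermediate filament gene ifb-2 (-2.92 ± 0.16) and the aspartic protease gene asp-1 (-2.57 ± 0.33). Intestinal genes gave camera adjusted p = 9.71e-10 (adjusted p = 0.0757 with an estimated correlation). Of 22 lysosomal protease genes 12 fell and 2 rose (14 and 2 adjusted over the list alone). Lysosomal proteases gave camera adjusted p = 2.55e-07 (adjusted p = 0.107 with an estimated correlation). Of 6 vitellogenins 5 fell (5 adjusted over the list alone), vit-3 (-6.90 ± 0.69) included. Vitellogenins gave camera adjusted p = 2.51e-05 (adjusted p = 0.252 with an estimated correlation).

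Most mitochondrial ribosomal protein genes also fell in daf-2 worms. Of 70 mitochondrial ribosomal protein genes 65 fell (69 adjusted over the list alone), mrpl-12 (-1.70 ± 0.18) included, and of 43 respiratory chain genes 25 fell (28 adjusted over the list alone; 16 without daf-2 day 11 library 3), nduf-5 (-1.24 ± 0.14) included. Camera gave adjusted p = 9.67e-21 (adjusted p = 0.0757 with an estimated correlation) and adjusted p = 6.24e-07 (adjusted p = 0.491 with an estimated correlation). Of 12 mitochondrially encoded genes 1 fell (0 adjusted over the list alone; 6 with the block), and COX1 was at -0.89 ± 0.39 (adjusted p = 0.0735; adjusted p = 0.00749 with the block). Mitochondrially encoded genes gave camera adjusted p = 0.221. Camera also passed for mitochondrial chaperones, splicing genes, synthetases and proteasome subunits as lower (adjusted p = 0.00409, 0.000111, 0.000341 and 0.000384; adjusted p = 0.364, 0.364, 0.698 and 0.71 with an estimated correlation). Of 82 cytosolic ribosomal proteins 9 fell and 3 rose (4 and 1 adjusted over the list alone; 40 fell with the block and 5 without daf-2 day 11 library 1 or library 3), rps-24 falling (-0.72 ± 0.15). Their camera adjusted p = 0.0262 did not hold (adjusted p = 0.84 with an estimated correlation; adjusted p = 0.0966 with upper-quartile scaling and 0.0867 with library size alone), nor without daf-2 day 1 library 1 (0.0691) or 2 (0.175) or daf-2 day 11 library 3 (0.189).

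Most DAF-16 class I genes rose in daf-2 worms and most class II genes fell. Of 18 DAF-16 class I genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), ftn-1 (3.03 ± 0.53) rising. Class I genes gave camera adjusted p = 0.000384 (adjusted p = 0.174 with an estimated correlation). Of 11 class II genes 8 fell (8 adjusted over the list alone), dod-19 (-1.93 ± 0.35) included, with a camera adjusted p = 0.000636 (adjusted p = 0.107 with an estimated correlation). Of 15 endoplasmic reticulum chaperones 11 rose (11 adjusted over the list alone), enpl-1 (1.08 ± 0.24) included. Chaperones of this list gave camera adjusted p = 0.00231 (adjusted p = 0.315 with an estimated correlation). Autophagy genes gave camera adjusted p = 0.0739 (0.025 with the block). Antimicrobial genes and lectins had medians of 0.30 and 0.11 while camera pointed down (adjusted p = 0.787 and 0.557).

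Some sperm genes rose in daf-2 worms: 10 of 54 passed (7 adjusted over the list alone), the median was 1.21 (2.52 without the libraries numbered 3), and camera gave adjusted p = 0.00146 (adjusted p = 0.741 with an estimated correlation). The count was 46 without the libraries numbered 3, 31 without daf-2 day 1 library 3, 5 without daf-2 day 1 library 1, and 6 without daf-2 day 1 library 2 or daf-2 day 11 library 1. The spermatogenesis regulator gene spe-44 was at 0.25 ± 0.31 (adjusted p = 0.55). Of the 5 male neuron and seminal fluid genes 2 rose (3 adjusted over the list alone), with a median of 2.15 and a camera adjusted p = 0.0935. Of 33 germline genes 10 fell (9 adjusted over the list alone; 20 with the block; 26 without the libraries numbered 3), spo-11 (-1.03 ± 0.19) included. Germline genes gave camera adjusted p = 0.00181 (adjusted p = 0.71 with an estimated correlation). Lists of histone, glycolysis, nucleolar, nuclear hormone receptor and F-box genes did not pass camera in daf-2 (adjusted p = 0.0548, 0.0548, 0.0514, 0.0548 and 0.0798) but passed with the block (adjusted p = 0.0244, 0.0223, 0.0175, 0.0249 and 0.0231) and without the libraries numbered 3 (adjusted p up to 0.0125).

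The age changes of the strains were compared gene by gene. Across 16698 genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.799 and Spearman's rho = 0.819, and their standard deviations were 1.364 in N2 and 1.368 in daf-2. Genes that rose in both numbered 2577, against 835 for independent lists, and genes that fell in both 2455 against 577; no library was shared between these comparisons. Of the 6958 genes called in N2, 6807 changed with the same sign in daf-2. Another 1916 genes passed in N2 alone and 1678 in daf-2 alone by the threshold, which does not show that they differ.

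The test of the difference itself, strain by age between days 1 and 11, was passed by 14 genes whose change was higher in daf-2 and 44 whose change was lower. Among genes taken by the naming rule the largest were the fatty acid and retinol binding protein gene far-3 (WBGene00001387, chromosome V from position 12996787), which went from 28.29 ± 14.8 to 184.1 ± 105 CPM in N2 (SD, n = 3) and from 127.6 ± 87 to 35.41 ± 11 CPM in daf-2, a difference of -4.55 ± 0.71 (log2, SE, n = 3 in each of 4 groups, adjusted p = 0.00648), and the insulin-like peptide gene ins-7 (WBGene00002090, chromosome IV from position 9682011). The level of ins-7 went from 2.018 ± 0.843 to 62.54 ± 6.26 CPM in N2 and from 0.7786 ± 0.282 to 1.386 ± 1.42 CPM in daf-2, a difference of -4.13 ± 0.71 (adjusted p = 0.0132; adjusted p = 0.0502 without daf-2 day 1 library 1). The glucuronosyltransferase gene ugt-18 (-3.27 ± 0.54, adjusted p = 0.00755), the gene nspc-20 (-3.01 ± 0.49, adjusted p = 0.00755), whose family holds near-identical copies that leave its counts uncertain, and ifb-2 (-1.62 ± 0.22, adjusted p = 0.00448) also changed lower in daf-2. The cathepsin B family gene cpr-4 had a difference of -3.63 ± 0.73 (adjusted p = 0.0337), asp-1 of -2.17 ± 0.44 (adjusted p = 0.0337) and pept-1 of -1.75 ± 0.38 (adjusted p = 0.0441). Differences in the other direction were found for the methyltransferase family gene comt-4 (3.70 ± 0.77, adjusted p = 0.0385), col-179 (1.88 ± 0.41, adjusted p = 0.0486), the fatty acid elongase gene elo-6 (1.78 ± 0.38, adjusted p = 0.043), the purine synthesis gene atic-1 (1.62 ± 0.31, adjusted p = 0.0245) and pcbd-1 (1.28 ± 0.27, adjusted p = 0.0378). Leaving out single libraries ended the calls of the last 8 genes, in between 7 and 12 of 12 cases each: the adjusted p reached 0.102 for cpr-4 without N2 day 1 library 2, 0.109 for asp-1, 0.16 for pept-1, 0.0775 for atic-1 and 0.134 for pcbd-1 without daf-2 day 11 library 2, 0.11 for comt-4 without daf-2 day 11 library 1, 0.159 for col-179 without N2 day 1 library 1 and 0.125 for elo-6 without N2 day 11 library 2. Other scalings, filters or fits also ended the calls of comt-4, col-179, elo-6, pcbd-1 and pept-1 (adjusted p up to 0.214, 0.195, 0.224, 0.195 and 0.233). The count of 58 genes was 19 without daf-2 day 11 library 1 and 97 without N2 day 1 library 3. It was 171 by DESeq2, 260 with the replicate block and 135 without the libraries numbered 3. In a fit of the compared groups alone it was 16, and far-3 (adjusted p = 0.0663), ins-7 (0.144), nspc-20 (0.108) and cpr-4 (0.0895) did not pass. The genes daf-2 (-0.30), sod-3 (0.09), mtl-1 (0.52), tts-1 (-2.13, adjusted p = 0.158; adjusted p = 0.0404 with the block), hsp-16.2 (-1.79) and vit-2 (-1.14) did not pass.

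**Figure D4:**
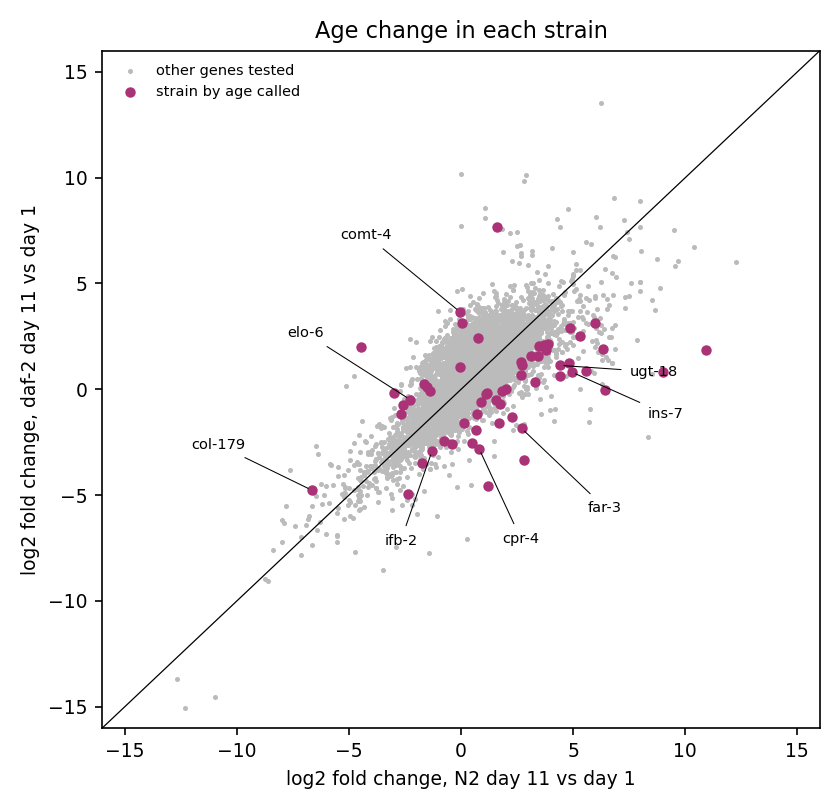
Log2 fold change between days 1 and 11 in N2 (x axis) and in daf-2 (y axis), with 1 point per tested gene, genes called in the strain by age test in purple and the line of equal change. Most genes lie near that line (Pearson's r = 0.799 across genes), and ins-7 lies at 4.94 in N2 and 0.81 in daf-2.

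By camera some lists differed between the strains in their change with age, none when the correlation was estimated. Of 66 antimicrobial genes 1, ilys-2, had a lower change in daf-2 (17 lower and 2 higher adjusted over the list alone), with a median difference of -0.83. Antimicrobial genes gave camera adjusted p = 1.17e-14 (adjusted p = 0.0745 with an estimated correlation). Of 17 intestinal genes 3 passed, ifb-2, asp-1 and pept-1, all lower (5 adjusted over the list alone). Intestinal genes gave camera adjusted p = 1.48e-08 (adjusted p = 0.0745 with an estimated correlation). Of 22 lysosomal proteases asp-1 and cpr-4 passed (8 lower adjusted over the list alone). Lysosomal proteases gave camera adjusted p = 7.8e-07 (adjusted p = 0.199 with an estimated correlation). Of 27 insulin-like peptides ins-7 and ins-10 passed, both lower (2 adjusted over the list alone), with a camera adjusted p = 0.00115 (adjusted p = 0.243 with an estimated correlation). Of 142 lectins 2 passed, both lower (2 adjusted over the list alone): clec-60 and clec-146 (-1.43 ± 0.31, adjusted p = 0.0482; adjusted p = 0.169 without daf-2 day 11 library 2 and up to 0.219 with other settings). Lectins gave camera adjusted p = 0.0114 (adjusted p = 0.459 with an estimated correlation; adjusted p = 0.0595 without a low-count filter, and 0.0553 and 0.0885 without daf-2 day 1 library 3 and daf-2 day 11 library 2). Further calls were col-179 among collagens (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.631), elo-6 and, lower, lipl-3 among fatty acid enzymes (3 and 2 adjusted over the list alone; camera adjusted p = 0.631) and ugt-18 among the cytochrome P450 and conjugation genes (1 adjusted over the list alone; camera adjusted p = 0.901). The genes ilys-2, ins-10, clec-60 and lipl-3 were named after their values were seen. In the other 35 lists edgeR called none of 1734 tested members, while 105 were at an unadjusted p under 0.05, DESeq2 called 8 and 17 passed adjusted over the list alone. Among these, sperm genes had the largest median difference (2.28, camera adjusted p = 2.32e-23; adjusted p = 0.243 with an estimated correlation; 1 adjusted over the list alone) and mitochondrially encoded genes one of 0.76 (camera adjusted p = 5.71e-06; adjusted p = 0.567 with an estimated correlation). Higher differences in daf-2 also passed camera for synthetases (adjusted p = 0.00149), cytosolic ribosomal proteins (0.0081), germline genes (0.0193), translation factors (0.0201), nucleolar genes (0.0201) and mitochondrial ribosomal proteins (0.04), and a lower one for yolk proteins (0.00952). None of the 7 passed when the correlation was estimated (adjusted p = 0.874 with an estimated correlation for synthetases, translation factors and nucleolar genes, 0.96 for cytosolic ribosomal and germline genes, 0.938 for mitochondrial ribosomal and 0.712 for yolk proteins), and in a fit of the compared groups only mitochondrial ribosomal and nucleolar genes missed the threshold (adjusted p = 0.0527 each). Without the libraries numbered 3 mitochondrial chaperones (adjusted p = 0.00893, against 0.0633) and respiratory chain genes (0.0477, against 0.384) also passed as higher, and oocyte (0.0101, against 0.172), class I (0.026, against 0.12) and muscle genes (0.0303, against 0.17) as lower. Leaving out 1 library ended each of the 7: the adjusted p reached 0.491 for synthetases, 0.586 for cytosolic ribosomal proteins, 0.766 for germline genes, 0.608 for translation factors and 0.692 for nucleolar genes without daf-2 day 1 library 3, 0.315 for mitochondrial ribosomal proteins without N2 day 1 library 2 and 0.112 for yolk proteins without N2 day 11 library 2. Some also ended without N2 day 1 library 1, N2 day 11 library 3, daf-2 day 1 library 1 or daf-2 day 11 library 1 or 2.

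The strains were next compared within each age. At day 1 the genes higher in daf-2 than in N2 included the lipase gene lipl-1 (17.1-fold, log2 4.10 ± 0.69, SE, n = 3 and 3, adjusted p = 0.00131), the heavy metal transporter gene hmt-1 (8.63-fold, 3.11 ± 0.29, adjusted p = 8.6e-07), the acetylcholine receptor subunit gene unc-38 (8.0-fold, adjusted p = 0.000122), rnh-1.3 (7.05-fold, 2.82 ± 0.23) and sdz-24 (5.91-fold, 2.56 ± 0.24). Also higher were mtl-1 (9.08-fold, 3.18 ± 0.60, adjusted p = 0.00398), tts-1 (6.24-fold, 2.64 ± 0.44) and sod-3 (4.56-fold, 2.19 ± 0.31, adjusted p = 0.000191), which stood at 30.83 CPM in daf-2 and 6.745 CPM in N2. Lower in daf-2 were the lectin genes clec-10 (14.4-fold, -3.85 ± 0.65) and clec-47 (4.08-fold, -2.03 ± 0.33), dod-24 (6.69-fold, -2.74 ± 0.53), the cathepsin B family gene cpr-5 (6.06-fold, -2.60 ± 0.52) and the peroxisomal oxidase gene acox-1.2 (3.99-fold, -1.99 ± 0.25). Values of daf-16 (-0.09 ± 0.36), hsp-16.2 (1.86 ± 1.01, adjusted p = 0.783) and vit-2 (0.11 ± 0.56) did not pass. By edgeR 191 genes were higher and 102 lower (427 and 236 with the block). The 293 calls were 105 when only these groups entered the fit, where lipl-1 (adjusted p = 0.05), clec-10 (0.0672), mtl-1 (0.127), cpr-5 (0.131) and tts-1 (0.159) did not pass, and 168 without daf-2 day 1 library 2, and cpr-5 did not pass without N2 day 1 library 1 (adjusted p = 0.0935) or daf-2 day 1 library 2 (adjusted p = 0.0653).

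Of 18 DAF-16 class I genes 8 were higher in daf-2 at day 1 (9 adjusted over the list alone), including the LEA protein gene lea-1 (2.19 ± 0.32). Their camera adjusted p of 1.08e-20 held when the correlation was estimated (adjusted p = 0.000385 with an estimated correlation), the only list of the 43 for which it did in the 5 main comparisons. Of 11 class II genes 3 were lower (3 adjusted over the list alone, with 1 higher). Class II genes gave camera adjusted p = 0.0014 (adjusted p = 0.147 with an estimated correlation). Of 27 insulin-like peptide genes 3 were higher (7 higher and 1 lower adjusted over the list alone; 6 higher with the block). Insulin-like peptides gave camera adjusted p = 5.31e-06 (adjusted p = 0.0889 with an estimated correlation). Of 352 F-box and MATH genes 10 were higher and 2 lower (18 and 4 adjusted over the list alone; 28 and 4 with the block; 17 without N2 day 1 library 3). Of the 10, 6 lie in a stretch of chromosome V at or near 0 in N2, and without the genes of that stretch, left out after seeing the data, 4 were higher. F-box and MATH genes gave camera adjusted p = 5.81e-05 (adjusted p = 0.00129 without the stretch; adjusted p = 0.878 with an estimated correlation; adjusted p = 0.266 without daf-2 day 1 library 3).

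In 26 of the 43 lists edgeR called none of the members at day 1 among 828 tested, with 13 at an unadjusted p under 0.05, 1 called by DESeq2 and 1 adjusted over the list alone. Of these lists, sperm genes (median -0.56, or -1.33 without the libraries numbered 3, adjusted p = 0.0118), proteasome subunits (0.0208), cytosolic ribosomal proteins (0.00178), mitochondrial ribosomal proteins (-0.16, adjusted p = 0.000536) and respiratory chain genes (0.00105) were lower in daf-2 by camera, each with adjusted p = 0.878 with an estimated correlation. For proteasome subunits the adjusted p was 0.129 in a fit of these groups only, 0.185 and 0.643 without N2 day 1 libraries 1 and 2, and 0.922, in the other direction, without daf-2 day 1 library 3. For cytosolic ribosomal proteins it was 0.246 without N2 day 1 library 2 and 0.652 without daf-2 day 1 library 3, for the respiratory chain 0.129 without N2 day 1 library 1 and 0.266 without daf-2 day 1 library 3, and for sperm genes 0.382 and 0.121 without N2 day 1 libraries 1 and 3 and 0.15 and 0.422 without daf-2 day 1 libraries 1 and 2. With the block mitochondrially encoded genes (adjusted p = 0.00794, against 0.0512), translation factors (0.00952, against 0.0582), synthetases (0.00952, against 0.0512), germline genes (0.0193, against 0.127) and mitochondrial chaperones (0.0193, against 0.121) also passed as lower. Without the chromosome V stretch synthetases, mitochondrially encoded genes (adjusted p = 0.0436 each) and lectins (0.0476, against 0.0512) passed as lower. Medians of the oocyte, cell cycle, splicing, neuronal and FMRFamide-like lists changed sign with library size alone.

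Lysozyme, lectin and protease genes were among those lower in daf-2 than in N2 at day 11. Lower were ilys-5 (269-fold, log2 -8.07 ± 1.28, SE, n = 3 and 3, adjusted p = 0.00041), ilys-2 (88.9-fold, -6.47 ± 0.82), clec-10 (84.6-fold, -6.40 ± 0.78), ins-7 (45.8-fold, -5.52 ± 0.54, adjusted p = 1.13e-06) and cpr-5 (39.0-fold, -5.29 ± 0.61). Higher in daf-2 were clx-1 (357-fold, 8.48 ± 1.38), spp-27 (60.6-fold, 5.92 ± 0.77) and icmt-1 (27.5-fold, 4.78 ± 0.62). The genes fbxb-7 and lsy-27 (WBGene00009834, chromosome V from position 17348665) were at 0 in all 3 N2 libraries and at least 719-fold and 608-fold higher in daf-2 (against 3 counts over the group). The genes mtl-1 (log2 3.70 ± 0.55, adjusted p = 0.000201) and sod-3 (4.86-fold, 2.28 ± 0.31, adjusted p = 7.6e-05) were again higher in daf-2, and tts-1 (0.51 ± 0.41, adjusted p = 0.712), hsp-16.2 (0.07 ± 0.87), daf-16 (-0.04 ± 0.36) and vit-2 (-1.03 ± 0.57, adjusted p = 0.436) did not pass. By edgeR 282 genes were higher and 373 lower (774 and 835 with the block). The 655 calls were 380 without daf-2 day 11 library 2 and 998 by DESeq2.

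**Figure D5:**
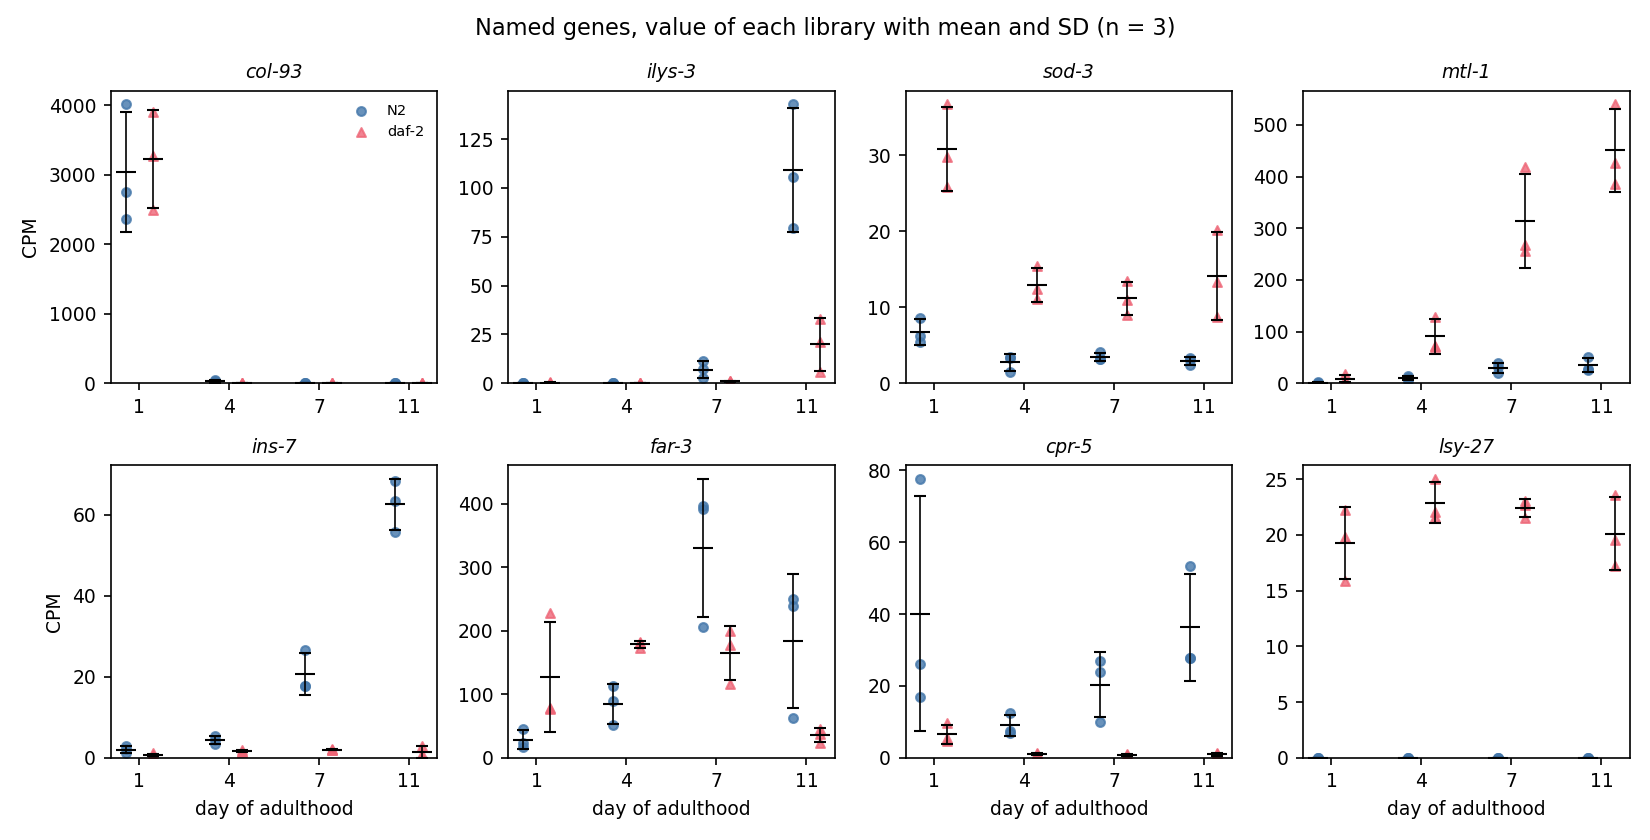
Level in CPM (y axis, linear, from 0) by day of adulthood (x axis) of 8 genes named in the text, with 1 point per library (circle, N2; triangle, daf-2) and the mean and SD of 3 libraries in black. The level of ins-7 reaches 62.54 ± 6.26 CPM in N2 at day 11 against 1.386 ± 1.42 CPM in daf-2, and lsy-27 is at 0 in all 12 N2 libraries.

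Of 22 lysosomal proteases 9 were lower in daf-2 at day 11 (10 lower and 3 higher adjusted over the list alone), including cpr-4 (-4.94 ± 0.59) and asp-17 (-4.07 ± 0.51). Lysosomal proteases gave camera adjusted p = 4.93e-08 (adjusted p = 0.0838 with an estimated correlation). Of 66 antimicrobial genes 12 were lower and 2 higher (26 and 3 adjusted over the list alone; 33 lower with the block and 6 without daf-2 day 11 library 2), nlp-34 lower (-2.55 ± 0.38). Antimicrobial genes gave camera adjusted p = 5.08e-10 (adjusted p = 0.0958 with an estimated correlation). Of 142 lectins 20 were lower and 8 higher (30 and 12 adjusted over the list alone), including clec-218 (-4.29 ± 0.41). Lectins gave camera adjusted p = 1.61e-05 (adjusted p = 0.0838 with an estimated correlation). Higher lectins numbered 3 without N2 day 11 library 2, 4 without N2 day 11 library 1, and 5 without N2 day 11 library 3 or any 1 of the daf-2 day 11 libraries. Of 17 intestinal genes 4 were lower, asp-1 (-2.64 ± 0.33), ifb-2 (-1.43 ± 0.16) and nhx-2 (-1.30 ± 0.17) included, and 1 higher (8 and 1 adjusted over the list alone; 9 lower with the block). Intestinal genes gave camera adjusted p = 7.73e-09 (adjusted p = 0.0595 with an estimated correlation). Of 18 class I genes 5 were higher, mtl-1 and dao-3 (0.94 ± 0.18) included, and 1 lower (11 and 1 adjusted over the list alone; 9 higher with the block). Class I genes gave camera adjusted p = 1.8e-08 (adjusted p = 0.0595 with an estimated correlation). Of 11 class II genes 3 were lower, dod-23 included (-3.30 ± 0.33), and 1 higher (3 and 1 adjusted over the list alone). Class II genes gave camera adjusted p = 0.00216 (adjusted p = 0.108 with an estimated correlation; adjusted p = 0.0798 without the libraries numbered 3). Of 6 vitellogenins vit-5 was lower (-2.41 ± 0.47; 3 adjusted over the list alone; 3 with the block). Vitellogenins gave camera adjusted p = 0.000731 (adjusted p = 0.436 with an estimated correlation). Of 54 sperm genes 1 was higher (1 adjusted over the list alone; 7 with the block; 2 without the libraries numbered 3), with a median of 1.79. Sperm genes gave camera adjusted p = 5.94e-13 (adjusted p = 0.436 with an estimated correlation).

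Other lists also held genes that differed at day 11. Of 352 F-box and MATH genes 16 were higher and 3 lower (18 and 3 adjusted over the list alone; 44 and 7 with the block), 6 of the 16 in the chromosome V stretch. The higher numbered 26 without the libraries numbered 3, 10 without daf-2 day 11 library 3 and 9 without N2 day 11 library 1 or 2, and 1 was lower without daf-2 day 11 library 2. F-box and MATH genes gave camera adjusted p = 2.1e-07 (adjusted p = 0.931 with an estimated correlation; adjusted p = 1.06e-05 without the stretch). The kinase gene sgk-1 was lower (-1.24 ± 0.21), the 1 gene called of 14 in the insulin pathway (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.622). In 20 of the 43 lists edgeR called none among 680 tested members, with 15 at an unadjusted p under 0.05, 0 by DESeq2 and 0 adjusted over the list alone. Of these, mitochondrially encoded genes were higher in daf-2 by camera (median 0.54, adjusted p = 0.0165; adjusted p = 0.931 with an estimated correlation), and respiratory chain genes passed as lower with the block (adjusted p = 0.0443, against 0.149). Mitochondrially encoded genes did not pass without N2 day 11 library 2 (adjusted p = 0.214) or daf-2 day 11 library 3 (adjusted p = 0.273). Antioxidant genes, 2 of them called and higher (4 adjusted over the list alone), passed as higher with the block (adjusted p = 0.0443, against 0.0774) and without the libraries numbered 3 (0.018), and glycolysis genes without these libraries (0.0115, against 0.149).

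The strains were also compared at days 4 and 7. At day 4 unc-38 was higher in daf-2 (3.92 ± 0.42) and lsy-27 at least 652-fold higher, and nspc-13 (-3.72 ± 0.46) and fat-7 (-2.88 ± 0.42) were lower; 261 genes were higher and 62 lower (633 and 190 with the block). At day 7 fbxb-7 and lsy-27 were at least 683-fold and 640-fold higher, and ilys-5 (-7.92 ± 1.17), clec-10 (-5.77 ± 0.74) and cpr-5 (-4.59 ± 0.59) were lower; 184 genes were higher and 166 lower (485 and 392 with the block). Over the 4 ages 64 genes were higher and 31 lower in daf-2 at every age, out of 946 called at 1 age or more; 16 of the 64 lie in the chromosome V stretch at or near 0 in N2. Among them hmt-1 was higher by 3.11, 2.90, 2.98 and 2.32 and rnh-1.3 by 2.82, 2.99, 3.19 and 2.91 on the log2 scale at days 1, 4, 7 and 11. Between days 1 and 11, which share no library, 77 genes were higher at both, 16 of them in that stretch, against 3.23 for independent lists, and 56 were lower at both against 2.28. The totals of 323 and 350 calls by edgeR were 178 without daf-2 day 4 library 2 and 182 without daf-2 day 7 library 2, and 186 at day 7 when only these groups entered the fit.

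Intermediate ages were compared within each strain. By day 4 in N2 col-92 (-7.99 ± 0.67), col-81 (-6.93 ± 0.72) and col-93 (-6.85 ± 0.54) had fallen, and catp-3 (2.23 ± 0.39) and hmit-1.1 (2.21 ± 0.47) had risen; in daf-2 col-93 (-9.19 ± 0.60) and col-94 (-6.58 ± 0.43) had fallen and mtl-1 had risen (3.31 ± 0.54). Muscle genes were already lower at day 4, with 23 of 35 fallen in each strain (26 in N2 and 25 in daf-2 adjusted over the list alone), and so were sperm genes, with 37 of 54 fallen in N2 and 33 fallen and 1 risen in daf-2 (42 and 38 fallen adjusted over the list alone). Camera gave adjusted p = 6.23e-27 and 1.3e-30 for muscle (adjusted p = 0.135 with an estimated correlation in N2 and 0.145 in daf-2) and adjusted p = 4.79e-20 and 1.18e-16 for sperm (adjusted p = 0.31 with an estimated correlation in N2 and 0.359 in daf-2). In all, 503 genes rose and 1013 fell in N2 and 703 rose and 836 fell in daf-2 by day 4 (3818 calls in daf-2 with the block). The share that rose was 33.2% in N2 and 45.7% in daf-2, and 52.9% and 57.1% with library size alone. By day 7 the calls were 2143 up and 2181 down in N2, with col-183 (9.19 ± 1.01) and dct-8 (6.29 ± 0.92) risen, and 2527 up and 2115 down in daf-2 (7529 with the block), with mtl-1 risen (5.11 ± 0.59); the share that rose in N2 was 49.6%, and 68.2% with library size alone. From day 4 to day 11, 2912 genes rose and 2035 fell in N2, ilys-3 rising (9.09 ± 0.72), and 2006 rose and 1384 fell in daf-2 (6287 with the block), ilys-3 rising (6.55 ± 0.68). Sperm genes rose over this interval, 36 of 54 in N2 and 48 of 54 in daf-2 (40 and 50 adjusted over the list alone), with camera adjusted p = 1.72e-06 and 3e-25 (adjusted p = 0.644 with an estimated correlation in N2 and 0.15 in daf-2). The share that rose was 58.9% in N2 and 59.2% in daf-2, and 72.9% and 75.3% with upper-quartile scaling. Without N2 day 1 library 1 the calls in N2 were 713 at day 4 and 2869 at day 7, without N2 day 11 library 2 they were 3250 from day 4 to day 11, and in daf-2 they were 922 at day 4 without daf-2 day 4 library 2 and 2208 from day 4 to day 11 without daf-2 day 4 library 1. Tests of strain by age at these intervals called few genes by edgeR: 0 between days 1 and 4 (408 at an unadjusted p under 0.05, 4 by DESeq2), 2 between days 1 and 7 and 33 between days 4 and 11, where cpr-4 (-4.14, adjusted p = 0.0154) and ins-7 (-4.05, adjusted p = 0.0142) were lower in daf-2. Their adjusted p reached 0.0655 for cpr-4 without daf-2 day 11 library 2 and 0.0521 for ins-7 without daf-2 day 4 library 2, and the counts of 2 and 33 were 11 without N2 day 1 library 3 and 4 without daf-2 day 4 library 2.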

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

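The splits within replicate numbers and the tests of males, of younger animals and of the spread between replicates were chosen after the results they bear on were seen, and what decides those of males and spread after their values were seen. Tests of the difference in age change between the strains picked out the counts of 2 genes between days 1 and 7, 58 between days 1 and 11 and 33 between days 4 and 11. Between days 1 and 11 the change was higher in daf-2 for comt-4 (log2 difference 3.7), col-179 (1.88), elo-6 (1.78), atic-1 (1.62) and pcbd-1 (1.28), and lower for far-3 (-4.55), ins-7 (-4.13), cpr-4 (-3.63), ugt-18 (-3.27) and nspc-20 (-3.01), and the list test picked out the sperm genes (median difference 2.28).

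Of 100 splits of the same libraries for each count, 11 gave 2 genes or more between days 1 and 7 (highest other 2304). Between days 1 and 11, 5 gave 58 or more (837), and between days 4 and 11, 8 gave 33 or more (109). Some kept the strains apart at 1 day, so they cannot decide about chance. With strains swapped within a number and day, 9, 5 and 6 of 32 splits gave as many (highest others 677, 878 and 997). With the block 8, 5 and 5 did (real counts 30, 260 and 182). These have the same limit. Between days 1 and 4 edgeR called 0 genes (408 at an unadjusted p under 0.05, 4 by DESeq2), a count that all 100 splits reach (highest other 1674), so they say nothing about chance. The split with 837 genes mixed the strains at day 1 but not at day 11. For the 12 comparisons of 3 libraries with 3, 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. The real counts and the highest others were, in N2, 1516 and 0 at day 4, 4324 and 1 at day 7, 6958 and 0 at day 11 and 4947 and 0 from day 4 to day 11, and in daf-2 1539, 4642, 6720 and 3390 with 0 each. Between strains they were 293 and 2 at day 1, and 323, 350 and 655 with 0 each at days 4, 7 and 11.

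Between days 1 and 11 the 54 sperm genes had a median log2 change of -1.06 in N2 and 1.21 in daf-2 (-0.28 and 2.52 without the libraries numbered 3). In both strains levels fell by day 4, then rose. Day 1 adults among day 11 daf-2 worms would restore day 1 transcripts. The 20 most abundant genes that fell at least 10-fold by day 4 were at 0.0146 of their day 1 level. Sperm genes were at 2.24 times theirs, which argues against day 1 adults. Larvae were not tested. Males cannot be told apart from a strain difference: the 5 genes of male neurons and seminal fluid had a median difference of 0.06 (quartiles -0.13 and 0.87) against 2.28 (1.85 to 2.65), with medians of 1.53 in N2 and 2.15 in daf-2, but 1 of the 5 reached 10 CPM, too few to decide. Spread between replicates cannot be told apart from it either. Exact two-sided permutation tests of the difference of 1.7 in log2 sperm counts gave p = 0.085 over 400 arrangements (lowest possible 0.005). Over 64 within replicate numbers p was 0.0938 (lowest 0.0312). Yet the difference was 2.15, 1.52 and 1.43 by number, and 3 of 1 sign allow no p under 0.25. At day 11 daf-2 was 1.3 higher (exact test p = 0.2). The strain itself remains open and was not tested.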

How the results depend on the processing

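Every other setting named with the methods was run; leaving out the libraries numbered 3 or the chromosome V stretch, and leaving out single libraries in the list tests, were chosen after seeing the data. Of 558 values of named genes none reversed under any alternative, and list tests moved most with an estimated correlation, under which 80 of 215 lost their call; leaving out the libraries numbered 3 ended 4 and gave 19. Refits that left out 1 library ended 51 calls of list tests and gave 111, and 5 refits reversed a list. As signed -log10 p, negative for lower in daf-2, these ranged between strains at day 1 from -1.651 to 3.764 for oocyte genes, -6.742 to 0.093 for proteasome subunits and -3.279 to 2.882 for muscle genes, and for strain by age from -1.943 to 1.629 for cell cycle genes. Calls of named genes were lost for 54 in a fit of only the groups compared, 32 with library size alone, 30 with upper-quartile scaling, 15 without a filter, 15 with protein-coding genes only, 14 without the libraries numbered 3, 10 with the stricter filter, 3 with RLE, 1 without the chromosome V stretch and 0 with DESeq2 or the replicate block, and in 318 of the refits that left out 1 library. The block gave calls in 8 results of named genes, myo-1 in daf-2 with age (adjusted p = 0.00148), plg-1 between strains at days 1 (0.0424) and 11 (0.0354) and tts-1 for strain by age (0.0404) among them, and for strain by age to the mitochondrial chaperone list (0.00385), and apart from these and the values in the results it changed no other call of a named gene in a paired comparison. Where a count moved by over 1.5 times, the cause was not tested.

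With only the groups compared in the fit the counts of genes were 947 and 2681 in N2 at days 4 and 7, 668 and 2535 in daf-2 at days 4 and 7, 105 and 186 between strains at days 1 and 7, and 0 and 16 for strain by age at days 7 and 11, the 0 standing beside 47 by DESeq2 at day 7. DESeq2 gave 502, 535 and 998 between strains at days 4, 7 and 11, and for strain by age 4, 47 and 171 at days 4, 7 and 11 and 122 from day 4 to day 11. With the replicate number as a block the counts were 3854, 7148 and 8143 in N2 at day 4, day 7 and day 11 against day 4, 3818, 7529 and 6287 in daf-2 likewise, 663, 823, 877 and 1609 between strains at days 1, 4, 7 and 11, and 30, 260 and 182 for strain by age at day 7, day 11 and day 11 against day 4. In N2 at day 4, day 7 and day 11 against day 4, and for strain by age, the numbers did not meet the condition for pairing, although every library correlated best with its own number. Without the libraries numbered 3 the counts were 3027 and 7658 in N2 at day 4 and day 11 against day 4, 6133 in daf-2 at day 11 against day 4, 990 between strains at day 11, and 4, 135 and 76 for strain by age at day 7, day 11 and day 11 against day 4. Library size alone gave 5 for strain by age at day 7.

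Leaving out 1 library at a time, the counts ranged in N2 from 713 to 1585 at day 4, 2869 to 4548 at day 7, 5543 to 7123 at day 11 and 3250 to 4468 from day 4 to day 11. In daf-2 they ranged from 922 to 1346, 3345 to 4699, 5167 to 7079 and 2208 to 3660. Between strains they ranged from 168 to 324 at day 1, 178 to 276 at day 4, 182 to 309 at day 7 and 380 to 604 at day 11, and for strain by age from 0 to 1 at day 4, 0 to 11 at day 7, 19 to 97 at day 11 and 4 to 36 from day 4 to day 11.

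Among genes called between days 1 and 11, 5009 changed in the same direction in both strains with no called difference (4118 to 5132 leaving out 1 library), 41 changed more in N2, 17 more in daf-2 and 10 in opposite directions. The count larger in N2 was 109 by DESeq2, 25 without a filter, 10 with only the groups compared, 158 with the block, 95 without the libraries numbered 3 and 11 to 75 leaving out 1 library. The count larger in daf-2 was 62, 6, 102 and 40 by DESeq2, with only the groups compared, with the block and without the libraries numbered 3, and 7 to 22 leaving out 1 library. The opposite count was 31 with the block, 35 without the libraries numbered 3 and 5 to 15 leaving out 1 library. Calls were not compared by depth.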

Other observations

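The tests of shared copies, of a smaller germline share and of depth, and what decides them, were chosen after the results they measure were seen. Of 691 tested pseudogenes 208 rose (30.1%) and 52 fell in N2 between days 1 and 11, where 22.1% of protein-coding genes rose, and 252 rose (36.5%) and 51 fell in daf-2, where 21.6% did. The difference in share was not tested. Of 86 non-coding RNA genes 26 rose and 10 fell in N2, and 30 rose and 4 fell in daf-2. The acetylcholine receptor gene unc-38 was higher in daf-2 by 3.92, 4.25 and 3.60 on the log2 scale at days 4, 7 and 11; on chromosome I it spans positions 4897620 to 4900974, beside icmt-1 from 4901918 to 4903264, which was 4.78 higher at day 11.

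Genes on the right arm of chromosome V were at 0 in all 12 N2 libraries and had counts in daf-2. Of 21 genes at 0 in N2 with at least 50 daf-2 counts over the genome (0 in the other direction), 20 lay between positions 17339084 and 17551209, where N2 held 14 counts in all and daf-2 39064; lsy-27 and fbxb-7 are among them. Counts shared between near-identical copies were argued against, since 1 of the 10 tested genes had counts that were not whole. A deleted or absent stretch in this N2 stock relative to the reference may be the source: within 50 kb of the region from lsy-27 to fbxb-7, 10 genes, these 2 included, had at least 50 counts in daf-2 and 0 in N2, although silencing of the stretch would give the same. No biological explanation was tested.

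Libraries numbered 3 stood apart in every group: 2868 genes were above and 3116 below their group mean in all 8. Depth was argued against, since library 3 held the most counts in 2 of 8 groups. A smaller share of germline would raise somatic markers alike, but beside germline lists at a median of -0.33, muscle genes lay at -0.28 (quartiles -0.47 and -0.14) and neuronal genes at 0.03 (-0.07 and 0.17), their quartile ranges 0.07 apart, which argues against it as the whole account. Gene length bias (rho = -0.22 across 16674 genes, which are not independent replicates) cannot be told apart from other differences between the libraries, because the size of the trend does not decide it. Differences between cultures stay open and were not tested.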
